A study of Danio rerio with 16 samples.

How the data were processed

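RNA was measured in testes of zebrafish of the AB strain, diploid or triploid, that were either controls or exposed to 17α-ethinylestradiol (EE2), a synthetic estrogen. The 16 libraries formed 4 groups of 4. Per the labels, total RNA was extracted from male gonads and made into strand-specific libraries after depletion of ribosomal RNA in place of poly-A selection. The dose and length of the exposure, the age of the fish, the number of fish behind a library and the time of sampling were not given in the sources used here.

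The deposited table held counts, raw read pairs per gene for each library. Per the file headers, the authors counted read pairs on the reverse strand over exons summed per gene with featureCounts 2.0.6, on STAR alignments, with the Ensembl 113 annotation of GRCz11. The command given there had no option for reads with several alignments or several overlapping genes, and featureCounts leaves such reads out by default. The STAR version and alignment settings were not given in the sources used here. The deposited table also held another kind of value, in other units than counts: the exon length of each gene in bases, used here only to select short genes.

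The table held 32520 genes, of which 29201 had a symbol in the reference used. Upper-case symbols were turned into zebrafish symbols where a RefSeq gene of that name, with or without a paralog letter, lay on the same chromosome. A paralog letter was added to 3626 genes in this way, and 1687 upper-case symbols were left as given. Symbols shared by several genes carry the Ensembl identifier. Library totals ran from 7052508 to 17369549 read pairs. Shares of counts in single libraries carry 95% Wilson intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules.

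Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, which left 23007 genes tested. Libraries were scaled by TMM factors, 1 mean per group was fitted by glmQLFit with robust estimation, and contrasts were tested with the quasi-likelihood F test. P-values were adjusted over all genes tested by Benjamini-Hochberg, and genes with an adjusted p under 0.05 were called changed. The median biological coefficient of variation was 20.3%. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts scaled to library size and TMM factor, and errors beside them are SD over libraries. The replicates differ in animals or pools that the labels do not describe, so p-values measure only the spread between samples.

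Triploid EE2 replicate 2 carries the word outlier in its own title. It was left out of the fit, which used 15 libraries, and its inclusion was an alternative. The comparisons were triploid against diploid in controls and under EE2, EE2 against control in diploids and in triploids, and the interaction of ploidy and EE2. The tests, the omission of the titled outlier, the gene lists, the rule for named genes and the alternatives, except those said to be added, were chosen before the data were examined.

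Lists of genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 26 lists within a comparison. Camera compares a list with the other genes tested. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. The lists were germ cells and spermatogonia, meiosis, spermatids and sperm flagellum, Sertoli cells, Leydig cells and steroidogenesis, oocytes, ovarian somatic cells, estrogen-responsive genes, hormone receptors, paracrine growth factors and receptors, retinoic acid metabolism and signalling, p53 targets, mitotic cell cycle, cholesterol synthesis, extracellular matrix, macrophages and neutrophils, lymphocytes, erythrocytes, liver, skeletal muscle, smooth muscle and peritubular cells, exocrine pancreas and gut, adipose tissue, endothelium, mitochondrially encoded genes, and acute stress response. Of 588 list symbols, 546 were matched to a gene. List members were also counted over all genes tested and adjusted over the list alone. Some genes belong to more than 1 list, such as amh, gsdf, igf3 and pgr. A list of 37 circadian clock genes was added after the data were seen.

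Named genes followed a rule with 3 parts. Part (a) took the 8 largest rises and 8 largest falls among changed genes with a mean log2 CPM of at least 1, a symbol that is not a clone name, and no overlap between the groups. Part (b) took 20 genes fixed whatever their result, of which 18 were tested and cyp19a1a and foxl2a were too low to be tested. Part (c) took the 3 members with the smallest p from each list with a changed member. The rule named 67 genes for ploidy in controls, 70 for EE2 in diploids, 36 for EE2 in triploids and 75 for ploidy under EE2. Genes named outside it are said to be chosen after their values were seen.

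Alternatives were DESeq2 size factors, library totals, no filter, a strict filter, inclusion of the titled outlier, a replicate block, fits on only the groups compared, a 2-fold minimum (log2 of 1), the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, and omission of each replicate. A pair of alternatives was added after the data were seen: omission of genes under 400 bases, and omission of both diploid control replicate 1 and diploid EE2 replicate 1. Other splits of the same libraries were refitted. The fit was tested on simulated data, in which 100 genes were shifted by a log2 of 1 and 100 by a log2 of 2. The shifted genes were drawn from those with an average log2 CPM above 1. Counts were drawn independently between libraries, so shifts shared by the genes of a library were not simulated. It recovered 54 and 92 of them for ploidy in controls, 62 and 90 for EE2 in diploids, 45 and 89 for EE2 in triploids, 43 and 92 for ploidy under EE2, and 23 and 85 for the interaction. Permutation tests used scipy 1.17.1, tables pandas 2.3.3 and plots matplotlib 3.10.9 in Python 3.11.15.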

Results

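Gene expression was measured by RNA sequencing of zebrafish testis in a design that crossed ploidy with exposure to 17α-ethinylestradiol (EE2). There were 4 libraries in each of the groups diploid control, diploid EE2, triploid control and triploid EE2. Replicates 1 to 4 held 7659779, 12454520, 8802380 and 13959219 read pairs in diploid controls and 7052508, 16416378, 17369549 and 8286209 in diploid EE2. They held 11628178, 11269636, 9556588 and 10707047 in triploid controls and 14155900, 11066002, 10022750 and 9431295 in triploid EE2. Triploid EE2 replicate 2, titled an outlier by the submitters, was left out of the comparisons, so that group had 3 libraries. Diploid control replicate 1 stood apart in its RNA. The signal recognition particle RNA rn7sl1 took 13.29% of its read pairs (95% Wilson interval 13.262% to 13.31%), against 5.23% to 6.96% in the other diploid controls. Its mitochondrial share was 6.86% (95% Wilson interval 6.847% to 6.882%).

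The comparison of triploid with diploid controls asked how testis expression differed with ploidy. Triploid testis had far less RNA of tssk6, a testis-specific serine kinase required for sperm function in mice, and of many pimr genes, a large zebrafish family related to the Pim kinases. It also had less amh, the anti-Müllerian hormone made by Sertoli cells. The level of tssk6 (ENSDARG00000017994, chromosome 22, 18386253 to 18387059, GRCz11) was 27.2 ± 15.7 CPM (SD, n = 4) in diploids and 0.207 ± 0.107 CPM (SD, n = 4) in triploids, a log2 change of -6.95 ± 0.62 (SE, adjusted p = 1.9e-05). The level of amh (ENSDARG00000014357, chromosome 22, 20747182 to 20761759) was 707 ± 134 CPM (SD, n = 4) in diploids and 159 ± 57.4 CPM (SD, n = 4) in triploids, a log2 change of -2.15 ± 0.28 (SE, adjusted p = 2.9e-04). The gonadal growth factor igf3 was higher in triploids, at 11.14 ± 9.96 CPM against 0.711 ± 0.0683 CPM (SD, n = 4 each), with a log2 change of 3.95 ± 0.87 (SE, adjusted p = 0.025). That call was lost in 6 of 8 omissions of a single library.

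Of the 8 largest falls under the rule for named genes, 7 were pimr genes. They included pimr177 (ENSDARG00000077035, chromosome 17, 10817675 to 10822175), from 22.3 ± 6.9 to 0.186 ± 0.0172 CPM (SD, n = 4 each), and pimr82, from 12.4 ± 4.02 to 0.115 ± 0.0398 CPM (SD, n = 4 each). The family was counted after these values were seen. It had 78 of 124 tested members lower and 1 higher, and the lower members lay on 17 chromosomes. The Fisher's exact test for an excess of pimr genes among the genes called lower gave a one-sided p = 2.93e-99, with genes treated as independent. The other largest rises were pimr19, pdlim5a, rad21l1, map3k14b, htr7, fibcd1b and vamp1a, with log2 changes from 1.05 to 1.96. The gene rad21l1, which encodes a meiotic cohesin subunit, rose by a log2 of 1.65 ± 0.37 (SE, adjusted p = 0.030). Among these rises, omission of a single library ended the call of fibcd1b in 8 of 8 cases and of pimr19 and htr7 in 7. It ended those of rad21l1 and vamp1a in 5, and those of pdlim5a and map3k14b in 0.

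Some lists of somatic cells and signalling were lower in triploid controls and others did not pass the test. The Sertoli cell list had 4 members lower, 1 higher and 10 not called, with 5 lower and 1 higher when adjusted over the list alone (median log2 -0.52, camera adjusted p = 0.0034, adjusted p = 0.25 with an estimated correlation). Its lower members included amh, gsdf, a Sertoli cell factor of the TGF-beta family (log2 -0.68, adjusted p = 0.020), and fshr, the receptor of follicle-stimulating hormone (log2 -0.96, adjusted p = 0.038). Omission of a single library ended the call of gsdf in 5 of 8 cases, of fshr in 7 and of amh in 0. The Leydig cell list had 2 of 20 lower (median log2 -0.44, camera adjusted p = 0.0055, adjusted p = 0.43 with an estimated correlation), and 6 lower when adjusted over the list alone. The paracrine list had 4 of 44 lower and 1 higher, with 11 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0033, adjusted p = 0.23 with an estimated correlation). It included gli1, a transcription factor of Hedgehog signalling, at log2 -0.92 (adjusted p = 0.0029). Retinoic acid genes had 2 of 18 lower, dhrs3a and the retinoic acid synthesising enzyme aldh1a2, and 5 lower when adjusted over the list alone (camera adjusted p = 0.0062, adjusted p = 0.23 with an estimated correlation). Smooth muscle had 1 of 13 lower, acta2, and 7 lower when adjusted over the list alone (camera adjusted p = 0.0033, adjusted p = 0.40 with an estimated correlation). Calls of dhrs3a, aldh1a2 and acta2 were lost in 2, 6 and 5 of 8 omissions of a single library. Hormone receptors had 2 of 21 lower, among them esr2a, an estrogen receptor (log2 -0.74, adjusted p = 0.0032), and 5 lower when adjusted over the list alone (camera adjusted p = 0.020, adjusted p = 0.43 with an estimated correlation). The call for hormone receptors was lost without diploid control replicate 4 (adjusted p = 0.072). Extracellular matrix (median log2 0.08, camera adjusted p = 0.72), endothelium (-0.18, camera adjusted p = 0.55), ovarian somatic cells (-0.02, camera adjusted p = 0.55), macrophages and neutrophils (-0.31, camera adjusted p = 0.25), lymphocytes (-0.21, camera adjusted p = 0.59) and adipose tissue (-0.68, camera adjusted p = 0.070) did not pass.

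The mitotic cell cycle list had 4 of 30 higher, among them bub1bb (log2 0.72), aurka (0.61) and plk1 (0.66), and 10 higher when adjusted over the list alone (camera adjusted p = 1.2e-07, adjusted p = 0.23 with an estimated correlation). Omission of a single library ended the call of bub1bb in 1 of 8 cases and of aurka and plk1 in 4 each. With the titled outlier included, 0 members were called and the list still passed (camera adjusted p = 3.2e-06). The meiosis list had 1 of 28 higher, rad21l1, also when adjusted over the list alone (median log2 0.15, camera adjusted p = 0.0034, adjusted p = 0.43 with an estimated correlation). The spermatid and flagellum list had a median log2 of 0.13 with a mean of -0.08 and only tssk6 of 35 called (camera adjusted p = 0.20). The germ cell marker ddx4 had a log2 change of 0.10 ± 0.11 (SE, adjusted p = 0.68). The liver list passed the test with 0 of 22 members called, also when adjusted over the list alone (median log2 0.40, camera adjusted p = 0.023, adjusted p = 0.83 with an estimated correlation). It was not called without diploid control replicate 1, 2 or 3 (adjusted p = 0.068, 0.14 and 0.15) or triploid control replicate 3 (adjusted p = 0.098).

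By the quasi-likelihood test with Benjamini-Hochberg adjustment, 630 of 23007 genes differed between triploid and diploid controls, 132 higher and 498 lower. A change of at least 2-fold was found for 16 of the higher and 336 of the lower genes. The total was 415 without diploid control replicate 3, 405 without diploid control replicate 4, 350 without triploid control replicate 1 and 387 without triploid control replicate 3. The balance of rises and falls varied with the test and the libraries. With 79% of the called genes lower here, the DESeq2 Wald test called 411 higher and 816 lower (66.5% lower) and limma-voom 392 higher and 701 lower (64.1% lower). Omission of both diploid control replicate 1 and diploid EE2 replicate 1, chosen after the data were seen, gave 463 higher and 596 lower (56.3% lower), and inclusion of the titled outlier gave 31 higher and 346 lower (91.8% lower). Of the 34 named genes called, 15 kept their call in every omission of a library, among them amh, tssk6, esr2a, gli1 and the 7 pimr genes of the largest falls.

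**Figure D1:**
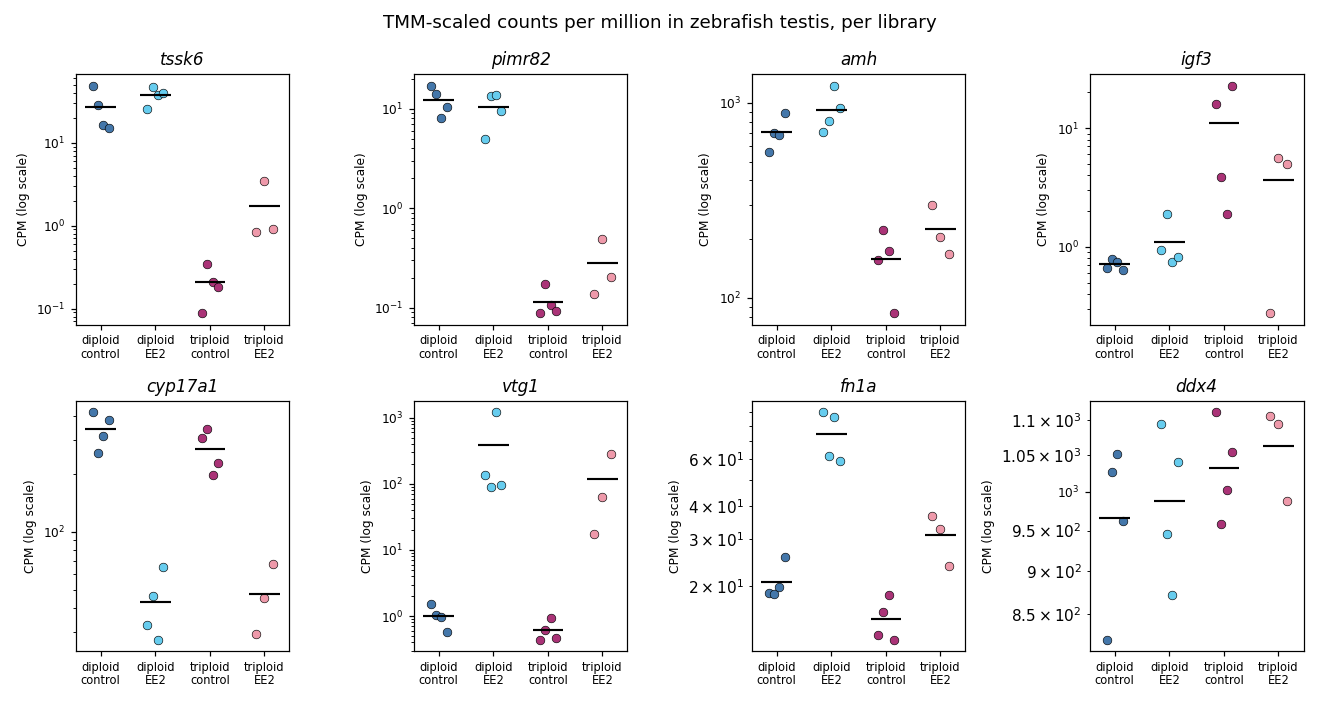
TMM-scaled CPM on a log axis for 8 genes in testis libraries of the 4 groups, where each point is a library and the bar is the group mean (n = 4, triploid EE2 n = 3). The levels of tssk6, pimr82 and amh were lower in triploids, at 159 CPM of amh in triploid controls against 707 CPM in diploid controls, and cyp17a1 was lower in both EE2 groups.

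The comparison of EE2 with control in diploids asked how the estrogen changed the testis. EE2 raised some estrogen-responsive genes and lowered some genes of androgen synthesis. The egg yolk precursor vtg1 (ENSDARG00000092233, chromosome 22, 24730965 to 24738188) was 1.01 ± 0.38 CPM (SD, n = 4) in controls and 386 ± 558 CPM (SD, n = 4) after EE2, a log2 change of 8.65 ± 1.28 (SE, adjusted p = 0.0031). The mean of vtg1 rested on diploid EE2 replicate 3, at 1222 CPM against 90.1 to 136.7 CPM in the other diploid EE2 libraries, and without it the log2 change was 6.81 (adjusted p = 0.0025). Among the diploid EE2 libraries the liver list was also highest there, at a log2 of 1.396 relative to the mean of the controls. In diploid EE2 replicates 1, 2 and 4 it was at 0.219, -1.164 and -1.478. Whether liver RNA in the samples added to vtg1 was not tested. The coagulation factor XIII A gene F13A1 (ENSDARG00000045453, chromosome 24, 2495197 to 2515623) rose by a log2 of 7.62 ± 0.56 (SE, adjusted p = 3.5e-05). The steroidogenic enzyme cyp17a1 (ENSDARG00000033566, chromosome 13, 28601195 to 28610965) went from 341 ± 71.7 to 43 ± 16.9 CPM (SD, n = 4 each), a log2 change of -2.99 ± 0.31 (SE, adjusted p = 3.6e-04).

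The list of Leydig cells and steroidogenesis had 8 of 20 members lower and 0 higher, and 10 lower when adjusted over the list alone (camera adjusted p = 2.5e-13, adjusted p = 0.044 with an estimated correlation). Beside cyp17a1, the lower members included hsd3b1 (log2 -3.22), the cholesterol transporter star (-2.40), CYP11A1 of ENSDARG00000092696, the side-chain cleavage enzyme (-2.21), and cyp11c1, of 11-ketotestosterone synthesis (-1.22, adjusted p = 0.043, lost in 6 of 8 omissions of a library). The Leydig cell hormone insl3 was 1103 ± 791 CPM in controls and 165 ± 130.3 CPM after EE2 (SD, n = 4 each; log2 -2.74, adjusted p = 0.056). The estrogen-responsive list had 7 of 17 higher and 9 higher when adjusted over the list alone (camera adjusted p = 3.1e-09, adjusted p = 0.14 with an estimated correlation). The other largest rises were vtg2, vtg5, a second F13A1 gene, the otolith protein gene stm, and the hemoglobin genes hbaa1 and HBE1. Values of hbaa1 and HBE1 rested on diploid EE2 replicate 1, without which their log2 changes were 2.01 against 4.47 and 2.03 against 4.43, and both calls were lost without any 1 of the diploid controls (adjusted p from 0.055 to 0.12). Without diploid EE2 replicate 3 the log2 changes were 4.37 against 6.50 for vtg2 and 3.96 against 5.87 for vtg5, and both calls were lost without diploid control replicate 1, 2 or 3 (adjusted p from 0.056 to 0.078). The other largest falls were prok2, lrtm2b, h1l1 and mctp1b.

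Several lists of somatic and blood cells were higher by camera, and of these smooth muscle and extracellular matrix also passed with an estimated correlation. Smooth muscle and peritubular genes had 7 of 13 higher, with 10 higher and 1 lower when adjusted over the list alone (median log2 0.88, camera adjusted p = 1.2e-20, adjusted p = 0.0062 with an estimated correlation). They included tpm2 (log2 1.44), myh11a (1.54) and acta2 (1.60), which encode proteins of the contractile apparatus. The extracellular matrix had 8 of 26 higher and 16 higher when adjusted over the list alone (median log2 0.77, camera adjusted p = 5.1e-18, adjusted p = 0.027 with an estimated correlation). Its members included fibronectin fn1a, from 20.9 ± 3.36 to 74.2 ± 16.1 CPM (SD, n = 4 each; log2 1.83), and the collagens col6a1 (1.29) and col5a1 (0.88). Endothelium had 5 of 18 higher and 12 higher when adjusted over the list alone (camera adjusted p = 1.8e-09, adjusted p = 0.12 with an estimated correlation). Macrophages and neutrophils had 2 of 19 higher and 8 higher when adjusted over the list alone (camera adjusted p = 1.2e-06, adjusted p = 0.28 with an estimated correlation). Erythrocytes had 1 of 8 higher and 8 higher when adjusted over the list alone (camera adjusted p = 5.1e-05, adjusted p = 0.28 with an estimated correlation). In diploid EE2 replicate 1 the erythrocyte list stood at a log2 of 4 above the mean of the controls, against 0.67 to 1.03 in the other diploid EE2 libraries. Without that library the median of the list was 0.72, against 2.33 with it, and that of endothelium was 0.54, against 0.83.

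Smaller shifts were seen in other lists. The progesterone receptor pgr (log2 1.13) and the nuclear receptor nr0b1 (1.75) were the 2 of 11 higher members of the ovarian somatic list, also when adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.25 with an estimated correlation). That call was lost without diploid control replicate 1, 2 or 3 (adjusted p = 0.051, 0.091 and 0.0502) or diploid EE2 replicate 2 (adjusted p = 0.095). Hormone receptors had 1 of 21 higher (camera adjusted p = 0.0067, adjusted p = 0.25 with an estimated correlation; adjusted p = 0.077 without diploid EE2 replicate 3). The paracrine list had 1 of 44 higher, pdgfra (camera adjusted p = 0.014, adjusted p = 0.25 with an estimated correlation; adjusted p = 0.062 without diploid EE2 replicate 3). The p53 list had 1 of 19 higher, plk3 (camera adjusted p = 0.0076, adjusted p = 0.25 with an estimated correlation). Lists of meiosis (median log2 -0.24, camera adjusted p = 0.0019, adjusted p = 0.32 with an estimated correlation), the mitotic cell cycle (-0.13, camera adjusted p = 0.0049, adjusted p = 0.36 with an estimated correlation) and spermatids (-0.17, camera adjusted p = 0.0052, adjusted p = 0.61 with an estimated correlation) were lower with 0 members called. The spermatid call was lost without diploid EE2 replicate 1 (adjusted p = 0.98). With both diploid control replicate 1 and diploid EE2 replicate 1 left out, meiosis did not pass (median -0.11, adjusted p = 0.10) and spermatids moved to 0.08 (adjusted p = 0.37).

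The remaining lists did not pass the test in diploids with all 15 libraries. Camera gave adjusted p = 0.30 for germ cells and spermatogonia, with 1 member higher, 0.10 for Sertoli cells, 0.61 for oocytes, 0.10 for retinoic acid genes, 0.41 for cholesterol synthesis and 0.71 for lymphocytes. It gave adjusted p = 0.76 for liver, 0.61 for skeletal muscle, 0.99 for exocrine pancreas and gut, 0.10 for adipose tissue, 0.092 for mitochondrially encoded genes and 0.61 for acute stress response. With both diploid control replicate 1 and diploid EE2 replicate 1 left out, germ cells and spermatogonia (median log2 -0.17, adjusted p = 0.024), retinoic acid genes (0.23, adjusted p = 0.042), adipose tissue (1.07, adjusted p = 0.0034), exocrine pancreas (-2.81, adjusted p = 0.042) and mitochondrially encoded genes (0.16, adjusted p = 0.042) passed. Without diploid control replicate 4, exocrine pancreas passed in the other direction (median log2 3.33, adjusted p = 0.0014). That library stood at a log2 of 4.445 for the list, relative to the mean of the controls. The other diploid controls stood at -1.518 to 0.244. Without diploid control replicate 1 alone, retinoic acid genes (adjusted p = 0.029) and adipose tissue (0.0015) passed. Single members of these lists rose, such as zbtb16a (log2 1.35), a marker of undifferentiated spermatogonia, and cyp26b1 (adjusted p = 0.0043), which degrades retinoic acid. The call of zbtb16a was lost in 5 of 8 omissions of a single library, and that of cyp26b1 in 0.

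By the quasi-likelihood test with Benjamini-Hochberg adjustment, EE2 changed 543 genes in diploids, 446 higher and 97 lower, of which 257 and 60 changed at least 2-fold. The total was 285 without diploid control replicate 2, 360 without diploid EE2 replicate 1 and 254 without diploid EE2 replicate 3. Of the 38 named genes called, 24 kept their call in every omission of a library, among them vtg1, cyp17a1, hsd3b1, star, fn1a, tpm2, myh11a and acta2.

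**Figure D2:**
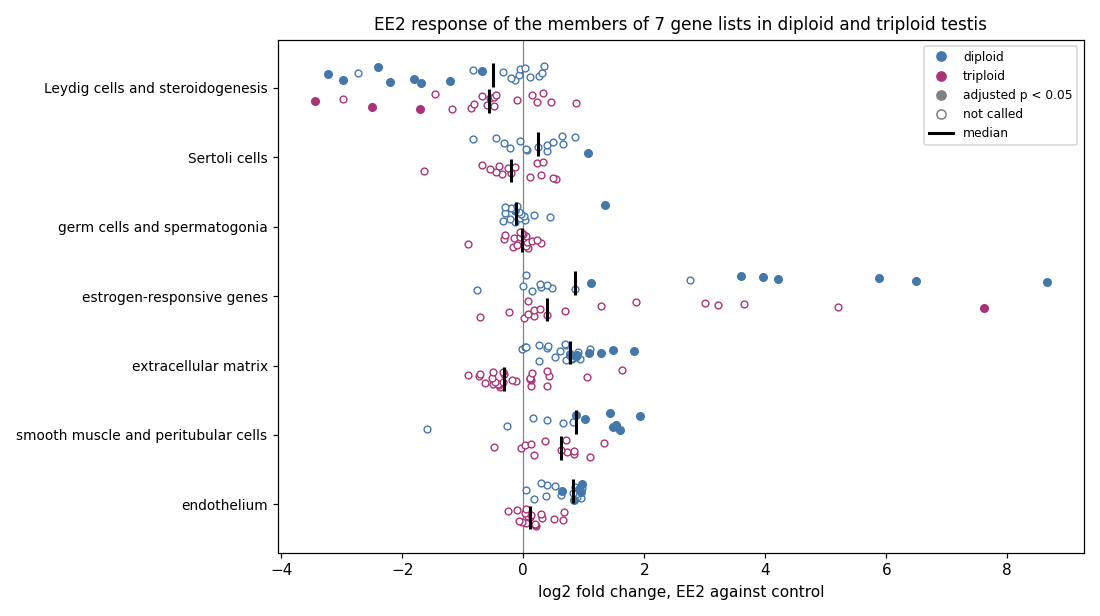
Log2 fold change of EE2 against control for the members of 7 gene lists, in diploid and triploid testis, where each point is a gene, filled points have an adjusted p under 0.05 and black bars are medians. Leydig cell genes had medians of -0.51 in diploids and -0.57 in triploids, and extracellular matrix genes had medians of 0.77 and -0.33, where the triploid list did not pass the test (camera adjusted p = 0.079) and had a median of 0.37 with the titled outlier included.

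The comparison of EE2 with control in triploids asked the same of triploid testis. The estrogen marker vtg1 was 0.613 ± 0.236 CPM (SD, n = 4) in controls and 120 ± 140.2 CPM (SD, n = 3) after EE2, a log2 change of 7.61 ± 1.30 (SE, adjusted p = 0.049). The call of vtg1 was lost in 7 of 7 omissions of a single library. The highest library was triploid EE2 replicate 4, at 279.8 CPM, and without it the log2 change was 6.03 (adjusted p = 0.17). The liver list was also highest there, at a log2 of 1.695 relative to the mean of the controls. Triploid EE2 replicates 1 and 3 stood at -0.971 and -0.543. Without replicate 4 the liver list passed the test (median log2 -1.098, camera adjusted p = 3.1e-07), against 0.202 with all 15 libraries (adjusted p = 0.50). Whether liver RNA added to vtg1 was not tested. F13A1 of ENSDARG00000045453 rose by a log2 of 5.37 ± 0.53 (SE, adjusted p = 0.0017). The steroidogenic gene cyp17a1 went from 267 ± 67 CPM (SD, n = 4) to 47.3 ± 19.3 CPM (SD, n = 3), a log2 change of -2.50 ± 0.34 (SE, adjusted p = 0.016), and hsd3b1 had a log2 change of -3.45 ± 0.50 (SE, adjusted p = 0.023). The other largest rises included cyp26b1 (log2 2.14), tbata, slco1f3, cald1b and anos1a, and the other largest falls included syt5a, mapk10, lrrc75ba, CYP11A1 of ENSDARG00000092696, slc4a4a and hspa8b. Values of insl3 gave a log2 change of -2.97 ± 0.78 (SE, adjusted p = 0.39).

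The Leydig list had 3 of 20 lower and 9 lower when adjusted over the list alone (camera adjusted p = 1.5e-16, adjusted p = 0.046 with an estimated correlation). Smooth muscle had 0 of 13 called, with 6 higher and 1 lower when adjusted over the list alone (median log2 0.63, camera adjusted p = 3.1e-10, adjusted p = 0.046 with an estimated correlation). Estrogen-responsive genes had 1 of 17 higher and 6 higher when adjusted over the list alone (camera adjusted p = 4.3e-07, adjusted p = 0.21 with an estimated correlation). Meiosis was lower with 0 of 28 called (camera adjusted p = 8.9e-06, adjusted p = 0.21 with an estimated correlation). Adipose tissue was higher with 0 of 11 called (camera adjusted p = 1.0e-05, adjusted p = 0.065 with an estimated correlation), and macrophages were higher with 0 of 19 called (camera adjusted p = 5.3e-04, adjusted p = 0.65 with an estimated correlation). Retinoic acid genes had 1 of 18 higher, cyp26b1 (camera adjusted p = 0.0062, adjusted p = 0.19 with an estimated correlation; adjusted p = 0.12 without triploid EE2 replicate 1). The paracrine list (camera adjusted p = 0.0097, adjusted p = 0.21 with an estimated correlation), skeletal muscle (0.0062, adjusted p = 0.34 with an estimated correlation) and exocrine pancreas (0.010, adjusted p = 0.70 with an estimated correlation) were lower with 0 members called. The paracrine call was lost without triploid EE2 replicate 3 (adjusted p = 0.075) and that of skeletal muscle without triploid control replicate 2 (adjusted p = 0.47). The pancreas call was lost without triploid control replicate 3 (adjusted p = 0.078) or triploid EE2 replicate 1 or 3 (adjusted p = 0.35 and 0.19). Inclusion of the titled outlier ended the calls of the paracrine list (median 0.04 against -0.05, adjusted p = 0.34), skeletal muscle (-0.71 against -1.30, adjusted p = 0.070) and exocrine pancreas (-0.23 against -0.94, adjusted p = 0.17). The extracellular matrix list did not pass (median log2 -0.33, camera adjusted p = 0.079), and its median was 0.37 with the titled outlier included (adjusted p = 0.059). That inclusion brought spermatids (adjusted p = 7.1e-04), the mitotic cell cycle (5.1e-06), lymphocytes (0.028) and endothelium (0.0071) past the threshold.

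By the quasi-likelihood test with Benjamini-Hochberg adjustment, EE2 changed 24 genes in triploids, 14 higher and 10 lower, and 1248 genes had an unadjusted p under 0.05. Without triploid control replicates 1 to 4 in turn the total was 4, 13, 15 and 5. Without triploid EE2 replicates 1, 3 and 4 in turn it was 2, 5 and 6. Of the 16 named genes called, only F13A1 of ENSDARG00000045453 kept its call in every omission of a library.

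The comparison of triploid with diploid testis under EE2 asked how ploidy mattered in exposed fish. The genes tssk6 (log2 -4.48 ± 0.54, SE, adjusted p = 2.3e-04), pimr82 (-5.26 ± 0.49, adjusted p = 1.0e-04) and nkd3l (-5.29 ± 0.70, adjusted p = 4.8e-04) were among the largest falls. The others were pimr180, pimr189, pimr173 and a pair of genes with the symbol KLHL10, and 80 of 124 pimr genes were lower. Sertoli cell factors were lower in triploids, with amh at 922 ± 224 CPM (SD, n = 4) in diploids and 224 ± 67.5 CPM (SD, n = 3) in triploids (log2 -2.04, adjusted p = 0.0011). The level of gsdf was 484 ± 53.4 CPM (SD, n = 4) against 167 ± 22.8 CPM (SD, n = 3; log2 -1.54, adjusted p = 1.1e-04). The largest rises were nkx2.7, fscn1b, cpo, tmprss4a, ppt2a.1, ccdc141, kcnk2b and mybpc3, with log2 changes of up to 2.05. Omission of a single library ended the call of ppt2a.1 in 7 of 7 cases, of tmprss4a in 6, of fscn1b in 4 and of the others in 2 or 3.

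The paracrine list had 14 of 44 lower and 0 higher, with 25 lower and 1 higher when adjusted over the list alone (median log2 -0.77, camera adjusted p = 1.1e-11, adjusted p = 0.0088 with an estimated correlation). The extracellular matrix had 13 of 26 lower, with 20 lower and 2 higher when adjusted over the list alone (median log2 -0.96, camera adjusted p = 6.6e-15, adjusted p = 0.030 with an estimated correlation). Its members included mmp14a (log2 -1.49), dcn (-1.29) and fn1a (-1.25). With the titled outlier included, fn1a had a log2 change of 0.90. Smooth muscle had 8 of 13 lower and 10 lower when adjusted over the list alone (camera adjusted p = 4.5e-12, adjusted p = 0.030 with an estimated correlation). Sertoli cells had 4 of 15 lower and 8 lower when adjusted over the list alone (camera adjusted p = 2.3e-06, adjusted p = 0.035 with an estimated correlation). Endothelium had 4 of 18 lower (camera adjusted p = 5.0e-06, adjusted p = 0.17 with an estimated correlation), and hormone receptors had 5 of 21 lower (2.2e-04, adjusted p = 0.12 with an estimated correlation). The mitotic cell cycle had 10 of 30 higher and 12 higher when adjusted over the list alone (camera adjusted p = 1.6e-10, adjusted p = 0.070 with an estimated correlation), among them kif11 (log2 0.88) and the cyclin ccnb1 (0.96).

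Further lists passed the test with weaker hold. Estrogen-responsive genes had 2 of 17 lower (camera adjusted p = 0.0019, adjusted p = 0.39 with an estimated correlation). Ovarian somatic genes had 3 of 11 lower and 1 higher (camera adjusted p = 0.017, adjusted p = 0.19 with an estimated correlation; adjusted p = 0.15 without triploid EE2 replicate 1). Omission of diploid EE2 replicate 1 ended the calls of meiosis (adjusted p = 0.067), spermatids (0.27), retinoic acid genes (0.053), p53 targets (0.067), cholesterol synthesis (0.077), macrophages (0.11), erythrocytes (0.053) and exocrine pancreas (0.067). With all 15 libraries these 8 lists had camera adjusted p from 9.3e-04 to 0.027 and adjusted p from 0.16 to 0.57 with an estimated correlation. Omission of other libraries also ended the calls of meiosis (adjusted p = 0.11 without triploid EE2 replicate 3), retinoic acid genes (0.10 without triploid EE2 replicate 4) and p53 targets (0.068 without triploid EE2 replicate 3). The same held for cholesterol synthesis (0.071 and 0.070 without triploid EE2 replicates 1 and 3) and exocrine pancreas (0.052 without triploid EE2 replicate 1). Inclusion of the titled outlier ended the calls of meiosis (adjusted p = 0.61), spermatids (0.45), retinoic acid genes (0.30), p53 targets (0.30), cholesterol synthesis (0.29) and macrophages (0.17), where the median of macrophages moved from -0.77 to 0.65.

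By the quasi-likelihood test with Benjamini-Hochberg adjustment, 1338 genes differed between triploid and diploid testis under EE2, 241 higher and 1097 lower. Of these, 30 and 606 differed at least 2-fold. The total was 878 without diploid EE2 replicate 1, 673 without diploid EE2 replicate 3, and 717, 592 and 655 without triploid EE2 replicates 1, 3 and 4. Of the 48 named genes called, 23 kept their call in every omission of a library, among them amh, gsdf, pgr, tssk6 and fn1a. The change of fn1a took the other sign when the titled outlier was included. Across genes, which are not independent replicates, the ploidy effects in controls and under EE2 had a Pearson correlation of 0.62 and a Spearman correlation of 0.45. In both, 46 genes were higher, against 1.38 if independent, 365 were lower, against 23.8 if independent, and 2 were called in opposite directions.

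The interaction of ploidy and EE2 asked whether the response to EE2 differed between ploidies. The response of extracellular matrix genes was lower in triploids than in diploids, with a median interaction of -0.91 on the log2 scale (camera adjusted p = 1.0e-25, adjusted p = 0.013 with an estimated correlation, fry adjusted p = 0.014). Of its 26 genes, 0 were called over all genes tested and 13 were lower when adjusted over the list alone. With the titled outlier included, the median was -0.31 (camera adjusted p = 7.5e-06). The paracrine list had a median of -0.27 (camera adjusted p = 6.3e-06, adjusted p = 0.053 with an estimated correlation), and smooth muscle had -0.60 (2.0e-06, adjusted p = 0.13 with an estimated correlation). Endothelium had a median of -0.62 (camera adjusted p = 5.3e-06, adjusted p = 0.34 with an estimated correlation), and -0.35 without diploid EE2 replicate 1. The Leydig list had a median of 0.13 and did not pass the test (camera adjusted p = 0.22). For cyp17a1 the interaction was 0.49 ± 0.43 (SE, adjusted p = 0.95), and for vtg1 it was -1.05 ± 1.93 (SE, adjusted p = 0.97).

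By the edgeR quasi-likelihood test 0 single genes had an interaction at an adjusted p under 0.05, and 1223 had an unadjusted p under 0.05. The DESeq2 Wald test called 43 and limma-voom 0. The edgeR total was 5 without diploid control replicate 4, 1 without triploid control replicate 2 and 2 without triploid control replicate 3. The calls by DESeq2 were 11 higher and 32 lower. The difference between 543 and 24 genes changed by edgeR was thus not shown gene by gene by edgeR or limma-voom. Whether the 43 genes called by DESeq2 belong to that difference was not examined. Across genes, which are not independent replicates, the EE2 effects in diploids and triploids had a Pearson correlation of 0.34 and a Spearman correlation of 0.30. In both, 13 genes were higher, against 0.27 if independent, 9 were lower, against 0.04 if independent, and 0 were called in opposite directions. Of the 543 genes changed in diploids, 471 had the same sign in triploids. Their median absolute log2 change was 1.112 in diploids. Counted in the direction seen in diploids, their median log2 change in triploids was 0.368. The 543 genes were selected by their diploid values, so these sizes are not on equal terms. The 22 genes called in both included vtg1, cyp17a1, hsd3b1 and cyp26b1, with interaction adjusted p from 0.69 to 0.99. These genes were selected by their calls in both, and the smallest edgeR interaction adjusted p of all genes was 0.1924. That range thus cannot show that their responses were alike.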

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

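Every test of a technical explanation in this part was chosen after the result was seen, as was the reading of the other splits of the libraries; the interaction tests of the lists and the omissions of single libraries were planned. The list levels below are mean log2 CPM over the list, relative to the mean of the 8 control libraries, and CPM values here are scaled over all 16 libraries.

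Many genes were lower in triploid than in diploid controls, and 78 of 124 pimr genes were among the 498. If reads had only moved between near-identical pimr copies, the family's summed level would have stayed alike, but it was 298 ± 32.2 CPM in triploid and 1648 ± 116 CPM in diploid controls (SD, n = 4 each), a log2 ratio of -2.47. The sum covers only the tested genes named pimr. Reads with several alignments were left out by default, so the sum cannot speak to reads lost in that way. A loss of all cells with flagellum genes would have lowered that list, whose median log2 fold was 0.133, and without diploid control replicate 1, with its unusual RNA, 406 of the 498 genes were again called lower, among 470 called lower in all. A variant carried by a family or line of the AB strain, named for every sample, cannot be told apart from ploidy here: 98% of the 498 genes also had a negative fold between the EE2 groups, as either would give, and they lay on all 25 numbered chromosomes. An effect of triploidy on late germ cells, or another origin of the triploid fish, stays open and was not tested.

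Extracellular matrix genes responded to EE2 less in triploids than in diploids, with a median interaction of -0.91 on the log2 scale. Blood or other tissue in diploid EE2 replicate 1 alone, where the erythrocyte list was high, would have carried the result, but without that library the median was -0.82. This omission cannot speak to blood in the other diploid EE2 libraries, whose erythrocyte levels were 0.668 to 1.029, against at most 0.427 in the controls. Whether more blood in that whole group added to the difference was not tested. A smaller share of germ cells in diploid EE2 testis would have raised all somatic markers alike, but Sertoli markers had a median log2 fold of 0.24 (15 genes) against 0.81 for matrix, smooth muscle and endothelium markers (57 genes), a difference of -0.575 (two-sided permutation p = 0.0042, 100000 resamples, genes treated as independent). More cells of the types that rose, or a response of Sertoli genes to EE2 itself, stays open. With the titled outlier included the median was -0.311, so the size of this difference may depend on which triploid EE2 testes are counted.

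Other lists also responded differently by the interaction test with camera, each given as a median log2 difference of the EE2 effect, triploid minus diploid. These were -0.27 for paracrine factors, -0.597 for smooth muscle, -0.624 for endothelium, -1.847 for erythrocytes, -0.236 for Sertoli cells, -0.443 for ovarian somatic genes, -0.685 for estrogen-responsive genes, -0.101 for p53 targets, -0.223 for macrophages and neutrophils, and 0.139 for spermatids. With an estimated correlation, their adjusted p ran from 0.053 to 0.67, so only extracellular matrix (adjusted p = 0.013) passed. Of 15 omissions of a single library, 10 ended the call for ovarian somatic genes (adjusted p up to 0.24, without triploid EE2 replicate 1), 7 that for p53 targets (up to 0.21, without triploid control replicate 4), and 6 that for macrophages (up to 0.67, without diploid EE2 replicate 1). The call ended in 5 omissions for spermatids (adjusted p up to 0.67, without diploid EE2 replicate 1), in 3 for Sertoli cells (up to 0.14, without diploid EE2 replicate 2) and in 3 for estrogen-responsive genes (up to 0.26, without diploid EE2 replicate 3). Without diploid EE2 replicate 1, where the erythrocyte level was 4.0 against 0.67 to 1.03 in the other diploid EE2 libraries, the median was -0.445 for erythrocytes and -0.347 for endothelium. With both replicates 1 of the diploid groups left out, erythrocytes stood at -0.398. With the titled outlier included, the call ended for Sertoli cells (adjusted p = 0.10), ovarian somatic genes (0.053), p53 targets (0.31) and spermatids (0.92), and macrophages moved to 1.074 (adjusted p = 0.022).

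Triploid EE2 replicate 2, which the comparisons did not use, had higher levels than all 15 other libraries in 6 lists. It stood at 3.46 for macrophages and neutrophils, against 1.75 in the next library, and at 1.47 for lymphocytes, against 0.65. It stood at 1.36 for extracellular matrix, against 0.88, at 0.79 for retinoic acid genes, against 0.62, at 0.48 for p53 targets, against 0.42, and at 0.37 for acute stress response, against 0.27. It was the lowest of all 16 libraries in 4 lists, at -0.843 for meiosis, against -0.544 in the next library, -1.625 for Leydig cells, against -1.365, -0.525 for the mitotic cell cycle, against -0.448, and -0.282 for cholesterol synthesis, against -0.253. The leukocyte gene ptprc was at 141.5 CPM, against at most 73.6 CPM elsewhere, and csf1ra, a macrophage receptor, was at 154 CPM, against at most 55.1 CPM, both chosen after their values were seen.

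Single libraries lay far from the rest of their group by Dixon's test in 14 of 216 groups tested, where chance gives about 1 in 20. Triploid EE2 replicate 2 held 4 of these: macrophages at 3.46, p53 targets at 0.48, the paracrine list at -0.04, and malat1 at 1.511% of read pairs (95% Wilson interval 1.504% to 1.518%). Diploid control replicate 1 had 18.97% of read pairs in genes under 400 bases (95% Wilson interval 18.944% to 19%) and a meiosis level of 0.01. Diploid EE2 replicate 1 had an erythrocyte level of 4.0 and 5.36 CPM of CYP11A1 of ENSDARG00000092696. Diploid EE2 replicate 4 had 6.44% of read pairs in small noncoding genes (95% Wilson interval 6.419% to 6.452%) and 9.59% in its 10 most abundant genes (95% Wilson interval 9.575% to 9.615%). Diploid EE2 replicate 3 had 1218.7 CPM of vtg1. Triploid control replicate 2 had a skeletal muscle level of 1.83, triploid control replicate 3 an erythrocyte level of -0.04 and triploid control replicate 4 21.07 CPM of esr2a.

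For 4 of the counts of changed genes, the real split gave more genes than any other split of the same libraries. With 35 splits, a share below 1 of 35 cannot be reached. Such splits also cannot speak to differences between families, tanks or pools of fish. For ploidy in controls, 1 of 35 splits of the libraries, the real one, gave 630 genes or more, and the highest other gave 1. For EE2 in diploids 1 of 35 gave 543 or more and the highest other gave 5. For EE2 in triploids 1 of 35 gave 24 or more and the highest other gave 5. For ploidy under EE2 1 of 35 gave 1338 or more, and the highest other, which set diploid EE2 replicates 1, 2 and 3 apart from the rest, gave 245. For the interaction the real count was 0, which all 100 splits drawn reach whatever the data, so the splits tested nothing there. The highest other gave 744, which points to a structure of the samples: that split exchanged the ploidy of most control libraries and of no EE2 library, so that the ploidy effect itself entered.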

How the results depend on the processing

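The omissions of genes under 400 bases and of diploid control replicate 1 with diploid EE2 replicate 1 were chosen after the data were seen, and the other alternatives were planned. The main totals were 630 genes for ploidy in controls, 543 for EE2 in diploids, 24 for EE2 in triploids, 1338 for ploidy under EE2 and 0 for the interaction. With a 2-fold minimum they were 352, 317 and 636 for ploidy in controls, EE2 in diploids and ploidy under EE2. With the titled outlier they were 377, 257, 38 and 484, and only fitting the groups compared gave 418 and 193 for ploidy in controls and EE2 in diploids. The DESeq2 Wald test gave 1227, 1207, 100, 2095 and 43, and limma-voom gave 1093, 1113 and 2122 for ploidy in controls, EE2 in diploids and ploidy under EE2. A replicate block gave 4 for EE2 in triploids. Without diploid control replicate 1 and diploid EE2 replicate 1 there were 1059 genes for ploidy in controls, 463 higher and 596 lower, and 1 for the interaction. With library totals, 29.4% of the genes changed by EE2 in triploids were lower, against 41.7%. Omitting single libraries gave 350 to 740, 254 to 656, 2 to 15, 592 to 1559 and 0 to 5, and a correlation of ploidy effects of 0.534 to 0.629, against 0.62. The correlation of EE2 effects was then 0.235 to 0.346, against 0.335. The 2-fold minimum lowered totals by construction; otherwise the cause was not tested.

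List tests passed in 61 of 130 cases, in 10 with an estimated correlation and in 30 by fry. Over the other alternatives and all lists, camera's direction changed in 115 of 2444 tests and a median's sign in 145. Of the 1217 that passed there or with the 15 libraries, the direction changed in 12 and the median's sign in 18. With the titled outlier, macrophages under EE2 moved to 0.653 for ploidy and 1.074 for the interaction, and fn1a to 0.901 for ploidy under EE2. Mitochondrial genes had an interaction of -0.226 with limma-voom and -0.241 to 0.445 when single libraries were left out. Spermatids ran from -0.017 to 0.255 for the interaction. Without both replicates 1, EE2 in diploids gave 0.079 for spermatids and 0.164 for mitochondrial genes, and the interaction gave -0.068 for spermatids and -0.281 for mitochondrial genes. In 3 of those 12 the median kept its sign: spermatids at 0.013 for the interaction with the titled outlier, against 0.139, spermatids for EE2 in diploids, from -0.27 to -0.035 when single libraries were left out, against -0.174, and pancreas for EE2 in diploids, at -2.814 without both replicates 1, against -0.427. In 9 others the median changed sign and camera's direction did not. The largest of the 9 shifts were for pancreas and liver. Pancreas for EE2 in diploids moved from -0.427 to 3.33 without diploid control replicate 4. Liver for EE2 in triploids moved from 0.202 to -1.098 without triploid EE2 replicate 4 and to -0.365 with a replicate block. The 9 also included, with the titled outlier, p53 targets (0.113) and meiosis (-0.106) for the interaction and the paracrine list for EE2 in triploids (0.04). Extracellular matrix for EE2 in triploids, which did not pass, moved from -0.326 to 0.369 with the titled outlier. The cause was not tested. No pairing by replicate number was seen: residuals of same-numbered libraries of different groups had a median correlation of 0 over 21 pairs (-0.162 to 0.114), against -0.012 over 63 other pairs. These correlations cannot exclude a shared tank or day, which the labels do not give. Recovery was simulated at this depth (7052508 to 17369549 read pairs), with 3 or 4 libraries per group. Among genes with an average log2 CPM above 1, 23 of 100 simulated interactions at a log2 of 1 were recovered. At a log2 of 2, 85 of 100 were. Changes in lower genes, and other depths, were not simulated.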

Other observations

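The list of clock genes and all tests in this part were chosen after the results were seen. Some genes of the circadian clock changed with EE2 in diploid testis. The nuclear receptor gene nr1d2a, a repressor in the clock, went from 18.9 ± 3.21 to 128 ± 25.9 CPM (SD, n = 4 each; log2 2.78 ± 0.30, SE, adjusted p = 3.9e-04). Of 37 clock genes tested, 11 were called, 7 higher and 4 lower. The higher ones included clocka (log2 0.82), a core activator, the cryptochromes cry3a (0.60) and cry3b (0.98), and nfil3-5 (1.25). The lower ones were per1b (-0.45), per3 (-0.52), ciarta (-0.56) and nr1d1 (-1.20). In triploids 0 of the 37 were called by the edgeR test, 1 by DESeq2 and 1 by limma-voom, and 9 had an unadjusted p under 0.05 by the edgeR test. The interaction of nr1d2a was -2.16 ± 0.42 (SE, adjusted p = 0.25). For the interaction 0 of the 37 were called by the edgeR test, 1 by DESeq2 and 0 by limma-voom, while 8 had an unadjusted p under 0.05 by the edgeR test, against a 95th percentile of 4 in 10000 random gene sets matched on mean expression. Between the ploidies under EE2, 9 were called by the edgeR test, 1 higher and 8 lower in triploids, against a 95th percentile of 5, with 10 by DESeq2, 9 by limma-voom, and 13 at an unadjusted p under 0.05, against 12. Between the ploidies in controls, 1 was called by the edgeR test, against 3, with 6 by DESeq2, 6 by limma-voom, and 14 at an unadjusted p under 0.05, against 11. Whether the response of these genes differed between ploidies stays open.

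The clock changes may reflect a different time of day of sampling. In diploids, 11 called genes exceeded the highest count, 6, in 10000 random gene sets matched on mean expression. In triploids the 0 called did not exceed the 95th percentile of random sets, 0, while the 9 at an unadjusted p under 0.05 exceeded theirs, 4. The requirement that triploids show it too was set when both counts were known, and diploids alone would have met the earlier form of the test. The time of sampling, which is not given in the sources used here, and an effect of EE2 on the clock cannot be told apart, since the treatment and any difference in time would fall on the same libraries.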
